A study of Mus musculus with 30 samples.

How the data were processed

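The values are the signal deposited by the authors, named CPM in the labels, in a single table with 1 column per library and no transformation. Each value was a whole number of reads times 1 constant per library, so whole reads were recovered for 100% of values within 0.02 of a whole read. The columns summed to 892246 to 1079916 and not to a fixed total, so the authors had applied a further scaling per library. They are called scaled CPM here, and 1 read was worth 0.038 to 0.0584 scaled CPM. The aligner, the counting tool, the genome build, the strand of the libraries and the scaling method are not given in the sources used here. Per the labels, total RNA was taken with TRIzol and libraries were made with an Illumina TruSeq RNA kit.

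The table listed 48709 genes, of which 19390 were above 0 in at least 1 library, with 12651 to 15581 per library. Of the gene names, 95.2% matched current GENCODE symbols, and older symbols were kept as given, so that myomaker appears as Tmem8c and myomixer as Gm7325. The 10 most abundant genes took 8.1 to 13.6% of the reads. Genes with 11 to 20 reads in 1 replicate were at 0 in another in 31.4% of pairs, where counting error alone gives 0.001%. Replicates correlated at 0.939 to 0.991 (median 0.982), with a chi-square per degree of freedom of 9.6 to 91.1, so no library was a copy of another. Intervals of shares are binomial and cover counting error only.

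Genes with at least 1 scaled CPM in at least 3 libraries were kept (12946). Values were taken as log2(CPM + 1) and fitted with limma on all 30 libraries, with a mean per group, 20 residual degrees of freedom and a mean-variance trend. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and "rose", "fell", "higher" and "lower" are used for genes that passed. Changes of effect between days were tested as differences of differences within the same fit. All adjusted p values of genes come from limma, and those of lists from camera in limma. The principal components were computed on the same values.

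The groups, comparisons, tests, thresholds and 37 gene lists were fixed before the data were examined. Of 740 list members, 725 were found by name, 12 by an older symbol and 3 were not in the table. A list was tested when at least 5 of its genes passed the filter, and the leukocyte list with 3 was not tested. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Adjusted p values of lists use the preset correlation unless stated, and were often much larger with an estimated one. Counts of called list members use p values adjusted over all genes, with counts adjusted over the list alone given where they differ. Medians are over all measured members.

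Named genes were chosen by rule. A set of 24 key genes was reported for each comparison of 5 µM with another dose whatever the result. Added to these were the 6 largest rises and 6 largest falls of each comparison among genes called, with a mean of at least 5 CPM in the higher group and replicates that did not overlap. Up to 4 called members of a list with the largest change completed the set. Some genes that met the rule are not reported here. Genes of the extra transcripts in the pair of day 1 libraries were chosen after the values were seen, from marker lists written before the test. Levels are means with the SD of 3 replicates.

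Each result was computed again with settings written down before the data were examined, namely other filters, other pseudocounts, median-of-ratios scaling, quantile normalization, robust variance estimates, a replicate term, each replicate left out in turn, only the groups of the comparison, and edgeR (quasi-likelihood) or DESeq2 on the recovered reads. Leaving out both libraries with extra transcripts was chosen after seeing the data. Overlaps were compared with the product of list sizes over all genes, and correlations of changes with 20 simulations that keep the shared controls.

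The tests were tested on simulated data built on the day 4 comparison of 5 and 0 µM, with 12717 genes and 200 of them changed. At 4-fold, limma recovered 84.8% of changed genes, edgeR 80.3% and DESeq2 84.8%. At 2-fold these were 61.2%, 62.7% and 67.2%. At 4-fold limma recovered 95.8% (46 of 48) of genes with at least 10 CPM and 55.6% (10 of 18) below, a split made after criteria set earlier, recovery above 90% and false calls below 12%, had failed. Of unchanged genes, 5.4% had an unadjusted p below 0.05. Among genes called, 13.7% were false for limma (20 of 146), above the nominal 5%, with 2.3% for edgeR and 11.8% for DESeq2. The changed list was found (adjusted p = 1.3e-82), and 0 of 200 random lists was called. Simulated genes were drawn independently, so this could not show false calls of lists whose genes are correlated. In the real data 64 list results were weaker and 368 the same with an estimated correlation.

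Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, statmod 1.5.0, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Raw sequence was not analysed here, so splicing, strand and the origin of the extra reads by sequence were left out. Apart from the extra transcripts, genes at 0 in every replicate of a compared group were not named.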

Results

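C2C12 myoblasts were followed through 4 days of myogenic differentiation with potassium chromate, a source of Cr(VI), at 0, 2 or 5 µM in the differentiation medium. The 30 RNA-seq libraries formed 10 groups of 3, with a day 0 group at 0 µM and a group at each dose on days 1, 2 and 4. The labels say only that the replicates are separate biological replicates. Whole reads recovered per library ranged from 18.5 to 26.9 M, and 12946 genes passed the level filter. The first principal component (41.3% of variance) ordered the days of differentiation, and the next (16.2%) separated 5 µM from control.

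**Figure D1:**
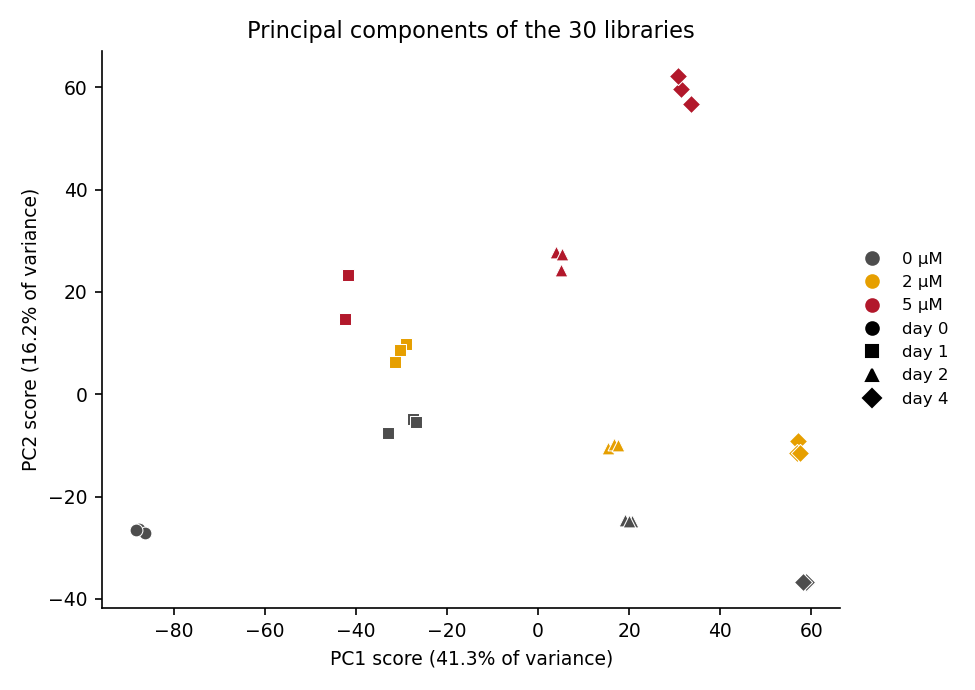
Scores of the 30 libraries on the first and second principal components of log2(CPM + 1), marked by dose and day. The first axis (41.3%) follows the day and the second (16.2%) sets the 5 µM day 4 libraries apart from the others.

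Mitochondrially encoded genes took a larger share of reads at 5 µM than in control on each day. In control cells the share was 6.67 ± 0.68% on day 0 and 10.09 ± 0.92% on day 4 (SD, n = 3), and at 5 µM it was 12.02 ± 0.66% on day 4. On day 1 it was 8.4 ± 0.39% in control and 10.15 ± 1.28% at 5 µM, and on day 2 it was 7.84 ± 0.71% and 10.33 ± 0.86%. At 2 µM it was 8.85 ± 0.79%, 8.27 ± 0.07% and 10.47 ± 0.95% on days 1, 2 and 4.

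A pair of day 1 libraries carried abundant transcripts that were at or near 0 in the other 28. In replicate 1 of 2 µM, Fabp4 stood at 2530 CPM, Hp at 2070 CPM, C3 at 1120 CPM and Adipoq at 158 CPM, and 82 genes reached 5 CPM there while staying below 1 CPM in every other library. The Y-linked genes Ddx3y (22.4 CPM), Eif2s3y (12.5 CPM), Kdm5d (6.34 CPM) and Uty (6.54 CPM) were read in that library, with a highest value of 0.379 CPM elsewhere. In replicate 3 of 5 µM, 185 genes met the same rule, among them Sftpc (199 CPM), Lyz2 (184 CPM), Calca (104 CPM) and Igkc (76.1 CPM). The other 28 libraries had 0 such genes. For day 1, values with both libraries left out are therefore given for counts, overlaps and the results they change. The fit uses 1 spread per gene over all 30 libraries, so both also entered the spread used on days 2 and 4. With both left out, the genes called at 2 µM went from 66 to 125 on day 2 and from 1145 to 1370 on day 4.

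**Figure D2:**
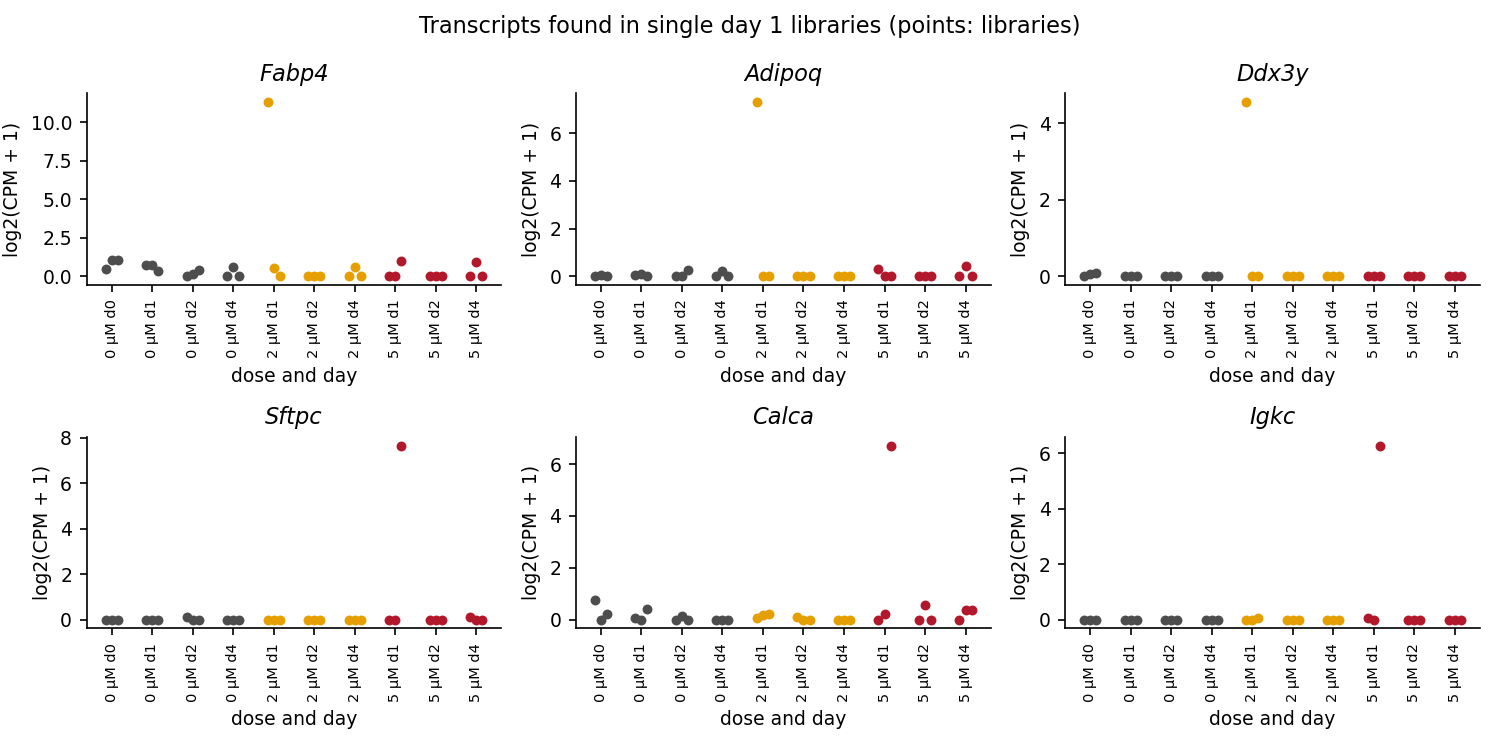
Level per library as log2(CPM + 1) of Fabp4, Adipoq, Ddx3y, Sftpc, Calca and Igkc by dose and day. Fabp4 reached 2530 CPM in 1 library at 2 µM on day 1 and Sftpc 199 CPM in 1 library at 5 µM on day 1.

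The transcripts of control cells turned from those of dividing myoblasts to those of contractile muscle cells over the 4 days. Genes for the contractile apparatus, for fusion and for calcium handling rose, while genes for division, ribosome assembly and antioxidant defence fell. In CPM, most of the sarcomeric increase came after day 1, whereas most of the fall of division genes was already present then. Against day 0, 6226 genes changed on day 1 (3285 higher, 2941 lower), 6713 on day 2 (3569 higher, 3144 lower) and 7736 on day 4 (3920 higher, 3816 lower). At 2-fold or more these were 1310 higher and 1068 lower on day 1, and 1937 higher and 1738 lower on day 4.

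On day 1 the muscle transcription factor Myog had risen from 3.10 ± 0.807 to 419 ± 15.6 CPM (SD, n = 3), a log2 change of 6.70 (adjusted p = 4.1e-30). Skeletal actin Acta1 rose by 6.76, cardiac actin Actc1 by 7.02, the light chain Mylpf by 6.91 and the RNA-binding gene Rbm24 by 6.02. The fusion gene Tmem8c (myomaker) rose by 6.13 to 165 ± 17.1 CPM and Gm7325 (myomixer) by 4.41. Mef2c rose by only 0.64 (adjusted p = 4.1e-04), and Myod1 (0.14, adjusted p = 0.29) and Myf5 (0.23, adjusted p = 0.11) did not pass. The cell-cycle inhibitor Cdkn1a rose by 2.20 to 685 ± 42.1 CPM. Id1, an inhibitor of myogenic transcription factors, fell by 2.66 and Ccnd1 by 2.62, from 608 ± 12.1 to 98.3 ± 12.1 CPM. Mki67 fell by 2.04 and Aurka by 2.64. Prl2c2 fell by 5.06, although reads of Prl2c2 and Prl2c3 cannot be cleanly assigned between the near-identical copies.

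By day 4 embryonic myosin Myh3 had risen by 10.04 to 1940 ± 306 CPM, Tnnt3 by 10.31 to 2180 ± 75.5 CPM and Mylpf by 10.55 to 6410 ± 1040 CPM. Mef2c, nearly flat on day 1, had risen by 6.52 to 752 ± 131 CPM. On day 2 it was at 105 ± 8.84 CPM, a log2 change of 3.69. Myf5 fell by 1.25 from day 0 to day 4, to 22.3 ± 2.56 CPM. Cdkn1a reached 2900 ± 311 CPM and the related inhibitor Cdkn1c rose by 5.67. Quinone reductase Nqo1 fell from 151 ± 10.9 CPM on day 0 to 24.0 ± 6.19 on day 1, 9.14 ± 1.54 on day 2 and 6.35 ± 2.36 on day 4. The ferritin gene Ftl1 fell by 3.37, Srxn1 by 3.48 and G6pdx by 3.41 by day 4. Log2 changes on the scale used here, log2(CPM + 1), understate the change of genes with low levels.

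The embryonic sarcomere list had 11 of 11 genes higher on each day, with medians of 4.75, 8.19 and 9.72. Of 32 adult sarcomere genes, 22 were higher on day 1, 31 on day 2 and 32 on day 4. Calcium-handling genes rose to 17 of 18 by day 4 and neuromuscular junction genes to 12 of 12. The G2/M list had 30 of 30 genes lower on each day and the G1/S list 27 of 28 on day 1. Of 28 NRF2 targets, 17 were lower and 4 higher on day 1 (18 and 5 adjusted over the list alone), and 23 were lower with 0 higher on day 4 (24 adjusted over the list alone). Ribosome biogenesis genes fell on day 1 (23 of 24 lower, with Dkc1 at −2.30 and Nop56 at −2.06). Cholesterol synthesis genes rose, 19 of 21 higher on day 1 and 16 on day 4. Unfolded protein and integrated stress response genes were lower on day 1 (17 of 30 lower, 2 higher, adjusted p = 4.1e-06) and not shifted on day 2 (adjusted p = 0.91). Notch targets rose on day 1 (8 of 13 higher, 1 lower), including Heyl (5.58) and Notch3 (2.71). Matrix genes had 18 of 32 higher and 6 lower on day 1 and 17 higher with 9 lower on day 4 (adjusted p = 0.085, and 0.58 with an estimated correlation). Col1a1 rose by 1.54 on day 1 and 2.93 on day 4.

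**Figure D3:**
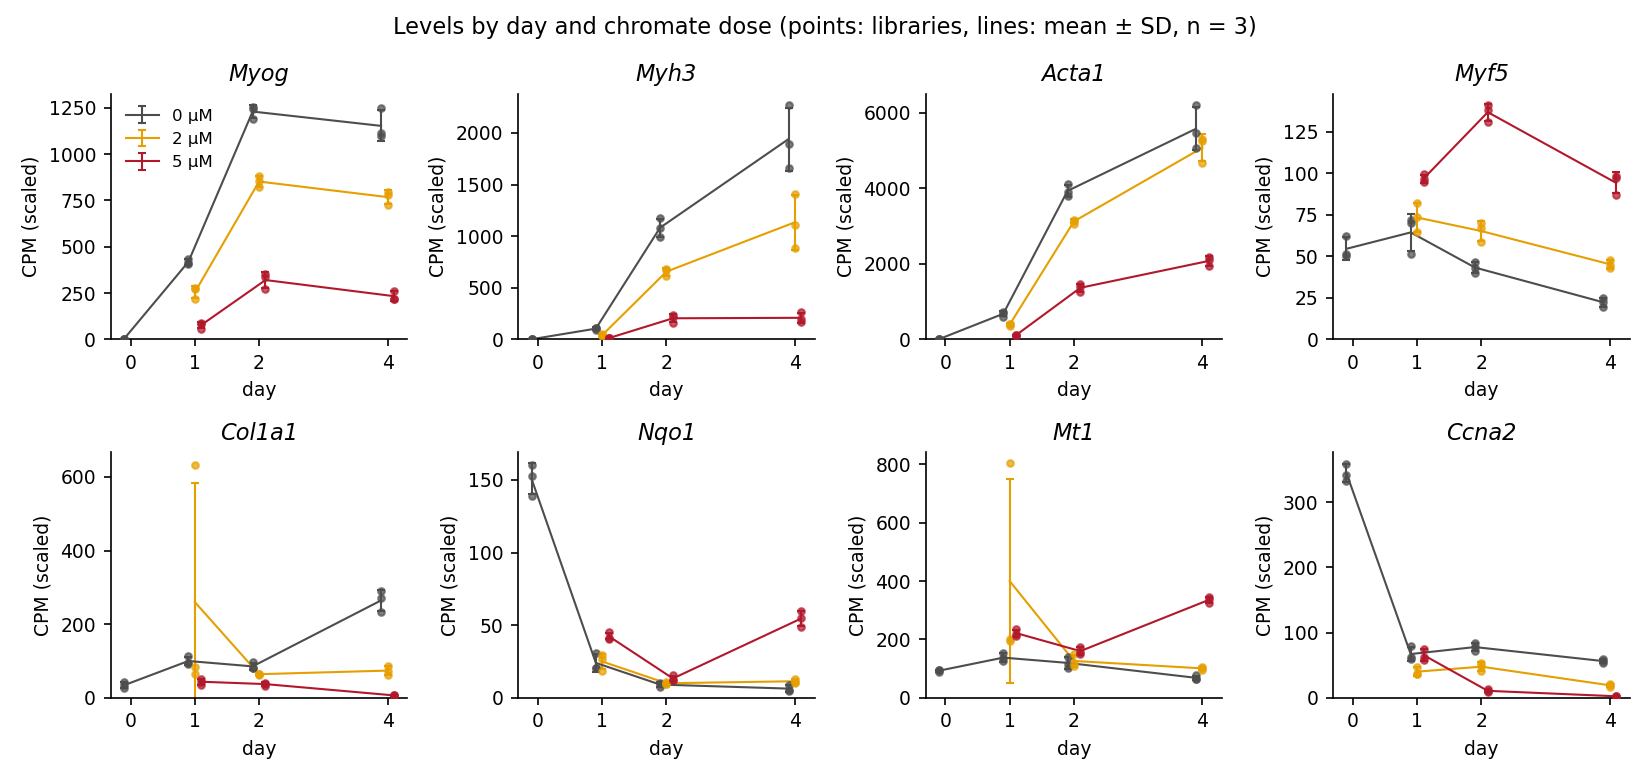
Level in scaled CPM (y) by day of differentiation (x, days 0, 1, 2 and 4) of Myog, Myh3, Acta1, Myf5, Col1a1, Nqo1, Mt1 and Ccna2 at 0, 2 and 5 µM, with points for libraries and lines for means ± SD (n = 3, error bars clipped at 0). Myog at 5 µM reached 233 ± 25.8 CPM on day 4 against 1150 ± 84.7 CPM in control.

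At 5 µM the muscle programme was already held back on day 1. Sarcomere, fusion and calcium-handling genes stood far below control, while antioxidant genes and p53 targets stood above it. Genes of DNA replication, of the unfolded protein response and of the matrix were also lower. In all, 556 genes were higher and 1218 lower, of which 95 and 314 by 2-fold or more. With both libraries carrying the extra transcripts left out, 553 were higher and 1138 lower, and 1392 genes were called in both fits.

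Myog fell by 2.45 (adjusted p = 2.5e-16), to 77.1 ± 17.2 CPM from 419 ± 15.6 CPM (SD, n = 3). Myh3 fell by 3.09 to 11.3 ± 1.98 CPM, Actc1 by 3.05 to 42.7 ± 7.40 CPM and Acta1 by 2.59 to 112 ± 12.6 CPM. Ckm, the muscle creatine kinase, fell by 2.63, Tnnt3 by 2.56, Myh1 by 2.18, Tmem8c by 1.93, Gm7325 by 1.82 and Mef2c by 1.69. Casq2 (−2.86), Neb (−2.81), Unc45b (−2.75) and Cacna1s (−2.73) were among the largest falls. Myod1 fell by 0.59 (adjusted p = 1.0e-04) and the acetylcholine receptor subunit Chrna1 by 0.34. Myf5 rose by 0.60 (adjusted p = 4.6e-04), to 96.7 ± 2.46 CPM from 64.3 ± 11.3 CPM. Id1 did not pass (−0.16, adjusted p = 0.68). The largest rises were Gm4149 (3.21), Cd24a (2.41, 47.7 ± 56.2 CPM from 5.07 ± 2.02 CPM), Trp53i11 (1.71) and the cytokine receptor gene Csf2rb (1.68, 10.3 ± 1.62 CPM from 2.55 ± 0.751 CPM). With both extra-transcript libraries left out, Cd24a rose by 1.47.

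Heme oxygenase Hmox1 rose by 0.57 (adjusted p = 0.014), Nqo1 by 0.82 (adjusted p = 0.0029), and the autophagy receptor Sqstm1 rose to 1350 ± 95.4 CPM from 637 ± 10.8 CPM. Ftl1 rose by 0.97 and Tkt by 1.11, while the transferrin receptor Tfrc fell by 1.10. Mt1 (0.68, adjusted p = 0.074) and Mt2 (0.94, adjusted p = 0.058) did not pass, and did with both libraries left out (0.69, adjusted p = 5.5e-05, and 1.02, adjusted p = 2.6e-07). How well the reads of these related metallothionein genes can be told apart was not checked here. Among p53 targets Mdm2 rose by 0.70, Trp53inp1 by 1.05 and Zmat3 by 0.71. Cdkn1a fell by 0.30 (adjusted p = 0.019), a call lost with both libraries left out (−0.24, adjusted p = 0.083). The muscle ubiquitin ligase Fbxo32 (0.32, adjusted p = 0.099) passed with both left out (0.42, adjusted p = 0.028). Ddit3 (0.22, adjusted p = 0.65) did not pass. Mki67 did not pass either (0.78, adjusted p = 0.34), at a level of 36.0 ± 48.3 CPM. The endoplasmic chaperone Hspa5 fell by 1.19, to 322 ± 11.2 CPM from 732 ± 14.0 CPM. Mthfd2 fell by 1.63 and Slc7a5 by 1.19. Col1a1 fell by 1.18 (adjusted p = 0.038).

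The embryonic sarcomere list had 11 of 11 genes lower (median −2.05, adjusted p = 2.2e-33). With both libraries left out the median was −1.89 (adjusted p = 8.1e-33, and 2.2e-05 with an estimated correlation). Adult sarcomere genes had 22 of 32 lower (20 with both left out), calcium-handling genes 16 of 18 (15 with both left out) and fusion genes 10 of 14 (9 with both left out). NRF2 targets had 12 of 28 higher and 0 lower (13 higher adjusted over the list alone, adjusted p = 5.7e-10), with the same counts with both left out. Of 30 p53 targets, 12 were higher and 2 lower (adjusted p = 1.5e-06), and 12 higher and 1 lower with both left out. G1/S genes had 16 of 28 lower (20 adjusted over the list alone), with Ccne1 at −1.48, and a list median of −0.83 with both left out. The G2/M list leaned up (2 of 30 higher, adjusted p = 0.030), a call lost with an estimated correlation (adjusted p = 0.49) and with both left out (median −0.04, adjusted p = 0.60). Unfolded protein and integrated stress response genes had 20 of 30 lower and 2 higher (22 and 4 adjusted over the list alone). Matrix genes had 18 of 32 lower and 1 higher (22 and 2 adjusted over the list alone), and cholesterol synthesis genes 15 of 21 lower (16 adjusted over the list alone). Smooth muscle genes had 9 of 11 lower, with Tagln at −1.26 and Acta2 at −1.07. DNA repair genes were not called (1 of 31 lower, adjusted p = 0.23) and were with both left out (6 lower, adjusted p = 0.026, and 0.13 with an estimated correlation). Heat shock genes (0 of 15 called by limma, adjusted p = 0.78) did not move.

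On day 2 at 5 µM the muscle genes remained low and the division genes collapsed. Genes of spindle assembly and DNA replication fell below the already low control level. NRF2 targets as a list were again higher, although Nqo1 and Hmox1 did not pass, and heat shock genes rose. In all, 1326 genes were higher and 1737 lower, of which 126 and 671 by 2-fold or more.

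Myog fell by 1.95, to 320 ± 40.9 CPM from 1230 ± 34.5 CPM (SD, n = 3), Mef2c by 2.10, Gm7325 by 2.35, Myh3 by 2.42 and Tnnt3 by 2.58. Acta1 fell by 1.53 to 1370 ± 107 CPM from 3930 ± 161 CPM, Ckm by 1.57, Myh1 by 1.48, Tmem8c by 1.13, Chrna1 by 0.40 and Myod1 by 0.38. Myoz2 (−3.56, 9.72 ± 1.75 CPM from 125 ± 8.38 CPM), Fst (−3.55), Myh7 (−3.26) and Myl4 (−3.20) were among the largest falls. Myf5 rose by 1.64 (adjusted p = 7.6e-13), to 137 ± 5.15 CPM from 43.2 ± 3.16 CPM. Among the largest rises were Clec3b (2.69), Hdc (2.30), the aldehyde dehydrogenase Aldh3a1 (2.33), the long non-coding RNA Zfas1 (2.14) and Tppp3 (2.47, to 636 ± 61.9 CPM from 114 ± 9.74 CPM).

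Mki67 fell by 2.05 (adjusted p = 0.0022), Birc5 by 3.06 to 3.44 ± 1.91 CPM from 33.0 ± 1.98 CPM, Cenpa by 3.26 and Ndc80 by 3.04. Fancd2 fell by 2.44 and Uhrf1 by 2.15. Aldh1l2 (−3.70), Asns (−2.45, to 34.9 ± 6.46 CPM from 193 ± 15.9 CPM), Mthfd2 (−2.49), Phgdh (−2.39) and Slc7a5 (−2.39) all fell. Tkt rose by 1.59, Gstm1 by 1.20 and Ephx1 by 1.16, while Slc7a11 fell by 1.48 and Tfrc by 1.14. Mdm2 rose by 0.30 and Fbxo32 by 0.67. Cdkn1a fell by 0.55, Hspa5 by 0.25 and Col1a1 by 1.18 (adjusted p = 0.025). Nqo1 (0.50, adjusted p = 0.057), Mt1 (0.42, adjusted p = 0.26), Mt2 (0.61, adjusted p = 0.20), Hmox1 (0.08, adjusted p = 0.80), Ddit3 (−0.17, adjusted p = 0.71) and Id1 (−0.37, adjusted p = 0.21) did not pass. Replicates of Mt1 did not overlap (149 to 175 CPM, against 103 to 141 CPM in control). The spread used for Mt1 included 804 CPM in replicate 1 of 2 µM on day 1.

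The G2/M list had 30 of 30 genes lower (median −2.47, adjusted p = 2.5e-46) and the G1/S list 23 of 28 lower and 1 higher (27 lower adjusted over the list alone). DNA repair genes had 17 of 31 lower and 1 higher (20 lower adjusted over the list alone). Embryonic sarcomere genes had 11 of 11 lower (median −1.96) and adult sarcomere genes 25 of 32. Unfolded protein and integrated stress response genes had 22 of 30 lower and 1 higher (23 lower adjusted over the list alone). NRF2 targets had 13 of 28 higher and 1 lower (17 higher adjusted over the list alone), and heat shock genes 9 of 15 higher and 1 lower (10 higher adjusted over the list alone, adjusted p = 0.0011), with Hspb1 at 0.87. Matrix genes had 18 of 32 lower and 3 higher (19 lower adjusted over the list alone, adjusted p = 3.9e-05, and 0.21 with an estimated correlation). Glycolysis genes had 7 of 17 higher (adjusted p = 0.0047, and 0.32 with an estimated correlation). Tagln fell by 2.66 among smooth muscle genes, of which 9 of 11 were lower.

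On day 4 at 5 µM most of the transcriptome differed from control. The muscle programme stayed low, division genes stayed far below control, and collagens and their partners collapsed, while NRF2 targets rose strongly, heat shock genes rose mildly as a list, and Mt1 and Mt2 rose. In all, 3529 genes were higher and 3699 lower, of which 1160 and 1814 by 2-fold or more.

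Nqo1 rose by 2.96 (adjusted p = 7.3e-15), to 54.7 ± 5.31 CPM from 6.35 ± 2.36 CPM (SD, n = 3). Mt2 rose by 3.25 to 545 ± 56.5 CPM from 56.3 ± 2.05 CPM, Mt1 by 2.28 to 335 ± 11.1 CPM and Hmox1 by 1.43 to 129 ± 10.2 CPM. Aldh3a1 rose by 4.79 to 216 ± 13.6 CPM, the glutathione transferases Gstm1 by 4.29 to 544 ± 12.5 CPM and Gsta4 by 3.11, and Ftl1 by 2.35 to 2200 ± 190 CPM. The water channel Aqp1 (4.68, to 460 ± 36.4 CPM from 17.0 ± 0.453 CPM), thrombomodulin Thbd (4.13), Stmn4 (4.21) and Fam102b (4.06) were the other largest rises. Ddit3 rose by 2.85, to 45.9 ± 3.69 CPM from 5.52 ± 0.783 CPM, Atf3 by 2.98 and Nupr1 by 1.93. Fbxo32 rose by 1.58 and Mdm2 by 0.52, while Cdkn1a fell by 0.72 and Hspa5 by 0.58. Hspa1b rose by 2.88, with its reads uncertain against the near-identical Hspa1a.

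Col1a1 fell by 5.14 (adjusted p = 3.7e-13), to 6.60 ± 1.38 CPM from 265 ± 28.0 CPM. Col6a2 fell by 5.19, Col6a1 by 5.14, Col5a3 by 4.33, Adam12 by 4.43, Tnc by 3.66 and Tagln by 5.26, to 5.85 ± 1.27 CPM from 259 ± 39.2 CPM. Dcn (2.24) and Clec3b (3.73) rose. Top2a fell by 4.12, Ccna2 by 4.08 to 2.39 ± 0.359 CPM from 56.3 ± 3.28 CPM and Mki67 by 2.46. Cdkn1c, an inhibitor of division, fell by 3.91, to 5.69 ± 2.11 CPM from 96.3 ± 11.0 CPM.

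Myog fell by 2.30, to 233 ± 25.8 CPM from 1150 ± 84.7 CPM, Myh3 by 3.23 to 209 ± 50.9 CPM from 1940 ± 306 CPM and Gm7325 by 2.95. Mef2c fell by 2.63, Tnnt3 by 2.51, Myh1 by 1.86, Ckm by 1.47, Acta1 by 1.42, Tmem8c by 1.19, Myod1 by 1.16, Id1 by 0.84 and Chrna1 by 0.59. Myf5 rose by 2.03 (adjusted p = 4.7e-16), to 94.1 ± 6.31 CPM from 22.3 ± 2.56 CPM. Pax7 fell by 1.40. The calpain Capn3 fell by 2.92, and the Notch receptor Notch3 by 2.88.

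Adult sarcomere genes had 30 of 32 lower (median −1.89, adjusted p = 2.1e-16), embryonic 11 of 11 (median −2.18), calcium-handling 18 of 18, fusion 13 of 14 and neuromuscular junction 12 of 12. NRF2 targets had 25 of 28 higher and 1 lower (median 1.70, adjusted p = 1.5e-14). Metallothionein and metal-transport genes had 6 of 10 higher and 2 lower (3 lower adjusted over the list alone, adjusted p = 0.029, and 0.054 with an estimated correlation). Heat shock genes had 12 of 15 higher and 1 lower (median 0.53). Matrix genes had 25 of 32 lower and 2 higher (26 lower adjusted over the list alone, median −1.94, adjusted p = 3.1e-13). G2/M genes had 30 of 30 lower (median −2.53), and G1/S genes 20 of 28 lower and 3 higher (4 higher adjusted over the list alone, adjusted p = 0.0012, and 0.27 with an estimated correlation). DNA repair genes had 15 of 31 lower and 3 higher (adjusted p = 0.028, and 0.27 with an estimated correlation).

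Other lists were mixed on day 4. Satellite and reserve cell genes had 10 of 14 lower and 2 higher (adjusted p = 0.0055, and 0.050 with an estimated correlation), and immediate early genes 12 of 21 higher and 4 lower (adjusted p = 0.022, and 0.086 with an estimated correlation). Unfolded protein and integrated stress response genes split, 9 of 30 higher and 16 lower (17 lower adjusted over the list alone, adjusted p = 0.10). Of 30 p53 targets, 12 were higher and 7 lower (adjusted p = 0.43), with Perp at 2.83 and Trp53inp1 at 1.72. Cholesterol synthesis genes had 9 of 21 higher and 7 lower, with a median of 0.03 and a mean of −0.16 (direction up, adjusted p = 1.00). Fibroblast genes had a median of −0.53 and a mean of 0.17 (direction up, adjusted p = 0.79), and NF-kB targets a median of −0.02 and a mean of 0.19. Oxidative phosphorylation genes (10 of 27 higher, 6 lower, adjusted p = 0.56) were not shifted. Adipocyte genes had 5 of 7 higher (adjusted p = 0.12), with Pparg at 2.34 and Lpl at 1.79.

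The response to 5 µM changed with the day of differentiation, and the change was tested directly as a difference of differences. Between days 1 and 2, 394 genes moved up and 357 down relative to control. Between days 1 and 4 these were 2142 and 1937, and between days 2 and 4 they were 1623 and 1451. With both libraries carrying the extra transcripts left out, 346 moved up and 335 down between days 1 and 2, and 2056 and 1870 between days 1 and 4.

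The metal and oxidant response grew late. From day 2 to day 4 the 5 µM effect grew for 22 of 28 NRF2 targets and fell for 1 (median 1.13, adjusted p = 2.6e-19, and 5.7e-04 with the estimated correlation), and for 6 of 10 metal response genes (median 0.87, adjusted p = 4.2e-04, and 0.0088). From day 1 to day 4 the effect grew by 2.14 for Nqo1 (adjusted p = 1.9e-07), 2.31 for Mt2, 1.60 for Mt1 and 0.85 for Hmox1. From day 1 to day 2 the same genes did not pass (Nqo1 −0.32, adjusted p = 0.62, and Mt2 −0.33, adjusted p = 0.81). From day 2 to day 4 the effect grew by 2.46 for Nqo1, 2.64 for Mt2, 3.02 for Ddit3 and 0.92 for Fbxo32. Across days 1 to 4 the effect on Ddit3 grew by 2.63 and on Fbxo32 by 1.27. The effect on Col1a1 fell by 3.95 from day 1 to day 4 (adjusted p = 9.6e-07), and by 3.96 from day 2 to day 4.

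Muscle genes parted in their course. The deficit of Acta1 eased by 1.17 and that of Ckm by 1.16 from day 1 to day 4, and that of Tmem8c by 0.74. The deficits of Gm7325 (−1.13), Mef2c (−0.94) and Myod1 (−0.57) deepened. Myog (0.15, adjusted p = 0.58), Myh3 (−0.14, adjusted p = 0.70), Myh1 (0.32, adjusted p = 0.48) and Tnnt3 (0.05, adjusted p = 0.82) did not pass over that span. Mef2c and Myh1 were low in day 1 controls (11.8 ± 2.14 and 12.9 ± 1.76 CPM). The log2(CPM + 1) scale understates deficits at such levels, so it can add to the deepening of Mef2c and hide an easing of Myh1. The excess of Myf5 grew by 1.44 (adjusted p = 3.4e-08). The deficit of Hspa5 eased by 0.61 and that of Cdkn1a deepened by 0.41. Mki67 moved by −3.24, and by −2.12 with both libraries left out. Chrna1 (−0.25, adjusted p = 0.099), Id1 (−0.68, adjusted p = 0.071) and Mdm2 (−0.18, adjusted p = 0.36) did not pass, and Chrna1 and Id1 did with both left out (−0.32 and −0.84).

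The 5 µM responses overlapped across days. Days 2 and 4 shared 1123 higher and 1492 lower genes, where 361.5 and 496.3 were expected from independent lists, and 59 genes moved in opposite directions. Days 1 and 2 shared 268 higher and 706 lower genes (56.9 and 163.4 from independent lists), and 290 and 691 with both extra-transcript libraries left out. On all 3 days 262 genes were higher and 666 lower, and 284 and 645 with both left out.

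At 2 µM on day 1 the muscle programme was already lower, more mildly than at 5 µM. Replication genes were lower as well, G2/M genes were lower as a list, and genes of glycolysis, hypoxia and antioxidant defence leaned higher. The counts changed most here with the library carrying the Fabp4 and Adipoq transcripts. In all, 67 genes were higher and 191 lower (18 and 24 by 2-fold or more). With only the groups of the comparison fitted, limma called 0 genes, with 1289 at unadjusted p below 0.05, and DESeq2 on all 30 libraries called 460. With both such libraries left out, 28 were higher and 87 lower, and 103 genes were called in both fits.

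Myog fell by 0.73 (adjusted p = 9.6e-04), to 254 ± 32.7 CPM from 419 ± 15.6 CPM (SD, n = 3). Myh3 fell by 1.32 to 41.1 ± 6.72 CPM, Neb by 1.26, Casq2 by 0.98, Tnnt3 by 0.95, Actc1 by 0.94, Acta1 by 0.79 and Ckm by 0.77. Cdc6, needed to license replication origins, fell by 1.79 to 2.28 ± 0.328 CPM from 10.3 ± 1.04 CPM, and Mcm3 by 1.18. Ephx1 rose by 0.66, Ftl1 by 0.54, Sqstm1 by 0.47 and Trp53inp1 by 0.67. Hspa5 fell by 0.38. Ak4 rose by 1.32 and Bnip3 by 1.06, and Bnip3 by 0.60 with both extra-transcript libraries left out. Mt1 rose by 1.19 (adjusted p = 0.0071) with a spread of 400 ± 350 CPM, and by 0.52 with both extra-transcript libraries left out (adjusted p = 0.020). Mt2 rose by 1.31 (adjusted p = 0.029), a call lost with both libraries left out (0.41, adjusted p = 0.15). The largest rises, Hsd11b1 (2.60, 19.3 ± 31.6 CPM), Mgst1 (2.29), Acaa1b (1.95), Lipe (1.95) and Vldlr (1.88), were also lost without both libraries, with Hsd11b1 at 0.99 (adjusted p = 0.18) and Lipe at 0.69 (adjusted p = 0.50). Myf5 (0.19, adjusted p = 0.53) and Col1a1 (0.59, adjusted p = 0.58) did not pass.

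Embryonic sarcomere genes had 8 of 11 lower with all libraries (10 adjusted over the list alone, median −0.63). With both libraries left out, 6 were lower (median −0.53, adjusted p = 1.1e-19, and 4.1e-04 with an estimated correlation). Adult sarcomere genes had 8 of 32 lower (14, and 20 adjusted over the list alone, with all libraries). G1/S genes had 7 of 28 lower (median −0.55), against 12 (21 adjusted over the list alone). G2/M genes had 2 of 30 lower (median −0.48, adjusted p = 6.0e-12, and 0.0068 with an estimated correlation), against a median of −0.56 with all libraries. Glycolysis genes had 4 of 17 higher (median 0.27), against 7 (12 adjusted over the list alone). Hypoxia genes had 3 of 17 higher (median 0.33), against 7 (12 adjusted over the list alone, median 0.63). NRF2 targets had 2 of 28 higher (median 0.18), against 3 (10 adjusted over the list alone). The adipocyte list was called up with all libraries (median 1.34, adjusted p = 2.4e-06, and 0.093 with an estimated correlation) and not without both (median 0.06, adjusted p = 0.83).

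At 2 µM on day 2 the change was small and shared its direction with 5 µM. A few antioxidant and muscle genes moved. In all, 34 genes were higher and 32 lower (2 and 5 by 2-fold or more). The total of 66 fell to between 19 and 31 when any 1 library of the comparison was left out, and was 181 by DESeq2. With both extra-transcript libraries left out it was 125 (56 higher, 69 lower), and with only the groups of the comparison fitted 324. Both of those libraries lie outside this comparison and act on it only through the shared spread.

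Aldh3a1 rose by 1.19, to 26.1 ± 4.91 CPM from 10.8 ± 1.28 CPM (SD, n = 3), with Lfng (1.10), Pde10a (0.93), Thbd (0.87) and Tppp3 (0.87). Gm7325 fell by 1.02, and Myoz2 fell to 58.5 ± 3.99 CPM from 125 ± 8.38 CPM. Tagln fell by 0.97, Myh3 by 0.72, Tnnt3 by 0.63, Mef2c by 0.62 and Myog by 0.53 (adjusted p = 0.045). Myf5 rose by 0.58 (adjusted p = 0.012). G2/M genes had 1 of 30 lower (22 adjusted over the list alone, median −0.61, adjusted p = 5.1e-25). Embryonic sarcomere genes had 4 of 11 lower (10 adjusted over the list alone, median −0.48), and NRF2 targets 3 of 28 higher (7 adjusted over the list alone).

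At 2 µM on day 4 the response was wider. NRF2 targets rose and division genes fell as lists. Many matrix and muscle genes were lower too, but these list shifts were lost with an estimated correlation (adjusted p = 0.13 for matrix, 0.12 for adult and 0.069 for embryonic sarcomere genes). In all, 661 genes were higher and 484 lower (106 and 145 by 2-fold or more).

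Clec3b rose by 2.70, Serpinb9b by 2.41 to 82.8 ± 13.4 CPM from 14.8 ± 2.72 CPM (SD, n = 3), Hdc by 2.35, Thbd by 2.27, Aldh3a1 by 2.25 and Aqp1 by 1.90. As3mt fell by 2.71, Cdkn1c by 2.66 to 14.5 ± 2.42 CPM from 96.3 ± 11.0 CPM, Fmod by 2.36, Cnr1 by 2.26 and Adam12 by 2.24. Gstm1 rose by 1.46 and Nqo1 by 0.80 (adjusted p = 0.0058), while Mt1 (0.56, adjusted p = 0.19), Mt2 (0.58, adjusted p = 0.33) and Hmox1 (0.35, adjusted p = 0.20) did not pass. Replicates of Mt1 (101 ± 5.14 CPM from 68.5 ± 7.90 CPM) and Mt2 (85.1 ± 13.7 CPM from 56.3 ± 2.05 CPM) did not overlap, nor did those of Hmox1. The spread used for Mt1 included 804 CPM in replicate 1 of 2 µM on day 1, so the missing call does not show an absent response. Col1a1 fell by 1.83, to 74.0 ± 11.3 CPM from 265 ± 28.0 CPM. Ccna2 fell by 1.51 and Top2a by 1.45. Myf5 rose by 0.99 (adjusted p = 3.1e-07). Myog fell by 0.58, Myh3 by 0.79, Gm7325 by 1.14, Mef2c by 0.68 and Tnnt3 by 0.55, and Acta1 did not pass (−0.13, adjusted p = 0.42).

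NRF2 targets had 11 of 28 higher (15 adjusted over the list alone, adjusted p = 4.0e-10) and G2/M genes 22 of 30 lower (28 adjusted over the list alone, median −0.98). Matrix genes had 14 of 32 lower and 3 higher (16 and 5 adjusted over the list alone, adjusted p = 1.2e-06, and 0.13 with an estimated correlation). Adult sarcomere genes had 10 of 32 lower (14 lower and 1 higher adjusted over the list alone, adjusted p = 3.4e-06, and 0.12 with an estimated correlation). The embryonic list had 3 of 11 lower (9 adjusted over the list alone, adjusted p = 1.4e-06, and 0.069 with an estimated correlation). From day 1 to day 4 the 2 µM effect moved up for 170 genes and down for 51, and for 126 and 38 with both extra-transcript libraries left out. Without replicate 1 of 2 µM on day 1 alone the total of 221 was 141. Among key genes it moved for Acta1 (0.66, adjusted p = 0.0033), Myf5 (0.80, adjusted p = 0.0062) and Col1a1 (−2.42, adjusted p = 0.013), and for Col1a1 by −1.39 with both extra-transcript libraries left out.

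**Figure D4:**
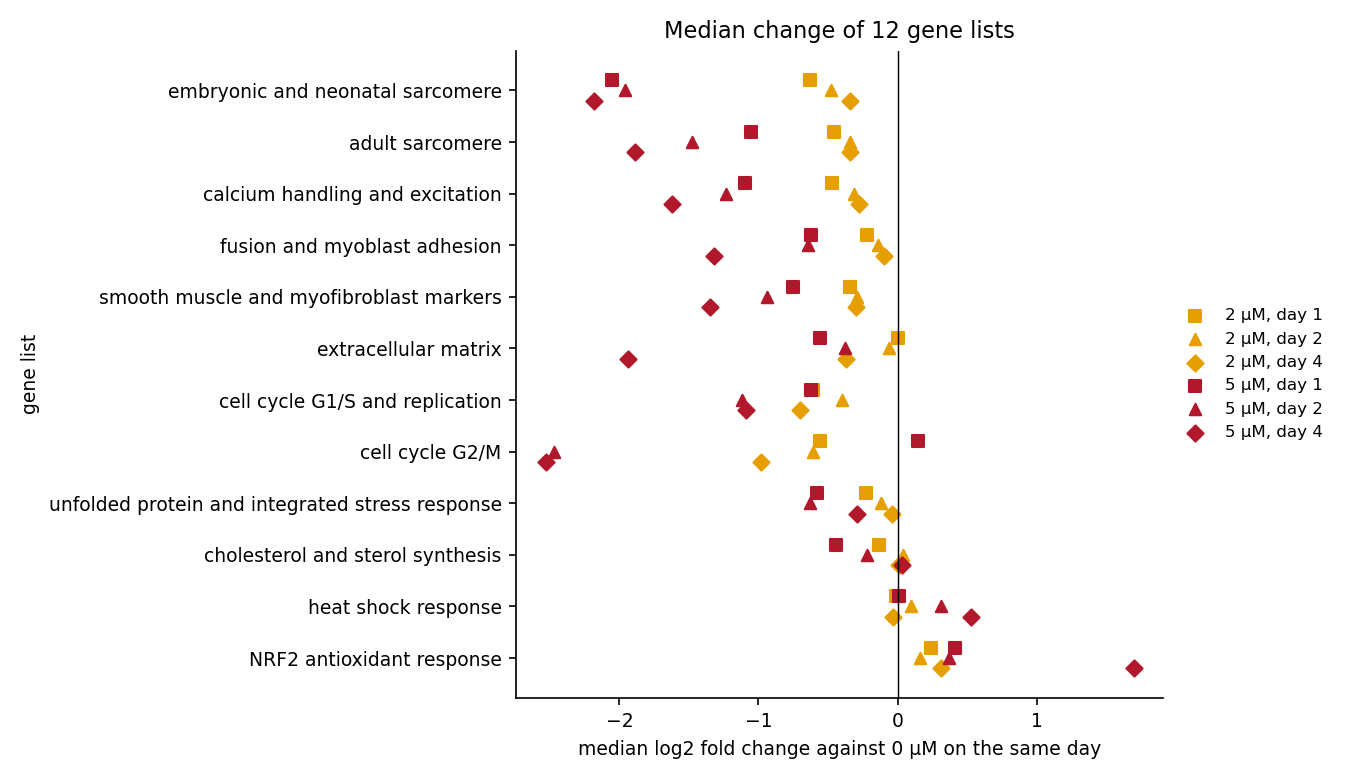
Median log2 fold change against control of 12 gene lists at 2 and 5 µM on days 1, 2 and 4. At 5 µM on day 4 the NRF2 list stood at 1.70 and the matrix list at −1.94.

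The higher dose differed from the lower one on every day, most on day 4. Muscle genes were lower at 5 than at 2 µM throughout. Division genes were lower from day 2, and G1/S genes already on day 1 with both extra-transcript libraries left out. NRF2 targets, heat shock genes, Mt1 and Mt2 were higher on day 4, and the NRF2 list was already shifted up on day 1. Between doses 167 genes were higher and 550 lower on day 1, 601 higher and 1052 lower on day 2, and 2947 higher and 3216 lower on day 4. With both extra-transcript libraries left out, 59 were higher and 346 lower on day 1, and with only the groups of the comparison fitted the total of 717 became 24.

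On day 1 Myog was lower at 5 µM by 1.72 (adjusted p = 6.3e-12), Acta1 by 1.80, Ckm by 1.86, Actc1 by 2.11, Myh3 by 1.77, Tnnt3 by 1.61, Gm7325 by 1.42, Tmem8c by 1.38, Myh1 by 1.33 and Mef2c by 1.19. Col1a1 was lower by 1.78, and by 0.76 with both extra-transcript libraries left out (adjusted p = 0.016), and Hspa5 was lower by 0.81. Mdm2 was higher by 0.38 (adjusted p = 0.017). The NRF2 list was shifted up (median 0.10, adjusted p = 0.0022). With both left out its median was 0.20, with 1 of 28 higher (adjusted p = 2.0e-06, and 0.017 with an estimated correlation). Nqo1 was higher by 0.76 (adjusted p = 0.013) and Myf5 by 0.40 (adjusted p = 0.038), calls lost with both left out (0.61, adjusted p = 0.17, and 0.33, adjusted p = 0.27). Myod1 (−0.26, adjusted p = 0.16), Chrna1 (−0.19, adjusted p = 0.19), Cdkn1a (−0.22, adjusted p = 0.17), Mt1 (−0.51, adjusted p = 0.28), Mki67 (1.36, adjusted p = 0.11), Fbxo32 (0.20, adjusted p = 0.42), Id1 (−0.16, adjusted p = 0.74), Hmox1 (0.07, adjusted p = 0.87) and Ddit3 (−0.02, adjusted p = 0.98) did not pass. G2/M genes had 14 of 30 higher (22 adjusted over the list alone, median 0.70), and 3 with both libraries left out (median 0.45, adjusted p = 2.1e-09). Against control, with both left out, this list was lower at 2 µM (median −0.48) and not shifted at 5 µM (median −0.04, adjusted p = 0.60). Mt2 did not pass (−0.37, adjusted p = 0.61), and stood higher with both left out (0.61, adjusted p = 0.0092). G1/S genes were not shifted with all libraries (median 0.03, adjusted p = 0.56). With both left out, 3 of 28 were lower (median −0.25, adjusted p = 0.0019, and 0.045 with an estimated correlation).

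On day 2 G2/M genes had 30 of 30 lower at 5 than at 2 µM (median −1.89). Tnnt3 was lower by 1.95, Myh3 by 1.70, Mef2c by 1.47, Myog by 1.42, Ckm by 1.40, Gm7325 by 1.34, Acta1 by 1.20, Myh1 by 1.02 and Tmem8c by 0.91. Mki67 was lower by 1.66, Cdkn1a by 0.59, Myod1 by 0.37, Hspa5 by 0.30, Chrna1 by 0.27, Aldh1l2 by 2.82, Trib3 by 2.37 and Chac1 by 2.14, while Myf5 was higher by 1.06 and Fbxo32 by 0.49. Mdm2 (0.28, adjusted p = 0.057), Mt1 (0.35, adjusted p = 0.45), Mt2 (0.68, adjusted p = 0.21), Nqo1 (0.37, adjusted p = 0.23), Col1a1 (−0.77, adjusted p = 0.22), Hmox1 (0.01, adjusted p = 0.99), Ddit3 (0.15, adjusted p = 0.81) and Id1 (−0.18, adjusted p = 0.67) did not pass. Replicates of Col1a1 did not overlap (32 to 41 CPM at 5 µM, 62.7 to 65.1 CPM at 2 µM). The spread used for Col1a1 included 633 CPM in replicate 1 of 2 µM on day 1, so the missing call does not show equal levels.

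On day 4 Mt2 was higher at 5 than at 2 µM by 2.67, Mt1 by 1.72, Nqo1 by 2.16, Ddit3 by 2.33, Fbxo32 by 1.39, Myf5 by 1.04, Mdm2 by 0.55 and the metalloproteinase Mmp3 by 3.70, and Hmox1 was higher too (adjusted p = 1.3e-06). Myh3 was lower by 2.44, Tnnt3 by 1.96, Mef2c by 1.95, Gm7325 by 1.81, Myog by 1.72, Myh1 by 1.49, Acta1 by 1.29, Ckm by 1.09, Tmem8c by 1.06, Id1 by 1.00, Myod1 by 0.96 and Chrna1 by 0.51. Mki67 was lower by 1.64, Cdkn1a by 0.69, Hspa5 by 0.41, Tagln by 4.15, Col6a1 by 3.80 and Col1a1 by 3.31. NRF2 targets had 22 of 28 higher and 1 lower (median 1.03), and matrix genes 27 of 32 lower and 1 higher (median −1.59). Heat shock genes had 11 of 15 higher and 1 lower (12 and 1 adjusted over the list alone, median 0.44, adjusted p = 7.0e-05), and G2/M genes 28 of 30 lower (29 adjusted over the list alone, median −1.63).

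Genes called at 2 µM moved mostly the same way at 5 µM. On day 1, 32 of 67 higher and 156 of 191 lower genes were shared, where 2.9 and 18 were expected from independent lists. With both extra-transcript libraries left out these were 21 of 28 higher and 75 of 87 lower (1.2 and 7.6 from independent lists). On day 2 all 34 higher and 32 lower genes were shared. On day 4, 546 of 661 higher and 434 of 484 lower genes were shared and 35 were opposite. Both doses used the same controls, and how many of the shared calls come from these was not separated. The correlation of log2 changes was 0.55, 0.67 and 0.63 on days 1, 2 and 4, where shared controls alone gave 0.50, 0.50 and 0.49. The covariance was 0.0808, 0.0948 and 0.229, where shared controls alone gave 0.0311, 0.0312 and 0.0306.

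Genes that rose at least 2-fold during control differentiation were shifted down by 5 µM. Of 1937 genes higher on day 4, 475 were lower and 50 higher at 5 µM on day 1 (median −0.18, and −0.21 with both extra-transcript libraries left out), and 716 were lower and 78 higher on day 2. Of 1594 genes higher on day 2, 932 were lower and 188 higher at 5 µM on day 4 (median −0.76). At 2 µM the 1937 genes were shifted down by camera on day 1 (102 lower, 19 higher, median −0.04, and −0.05 with both left out) and on day 2 (23 lower, 5 higher, median −0.10). On day 4 at 2 µM the 1594 genes were 143 lower and 102 higher (median −0.05), without a shift by camera, while the 561 of them that had risen at least 4-fold were shifted down, with 80 lower and 31 higher (median −0.17). Of the 1168 genes that fell by day 2 in control, 358 were lower and 361 higher at 5 µM on day 4, again without a shift by camera. On day 2 at 5 µM the 452 genes that had fallen at least 4-fold by day 4 in control were shifted down (182 lower, 66 higher, median −0.35), and all 1738 that had fallen at least 2-fold were not. At 2 µM on day 1 these 1738 were shifted slightly down (54 lower, 9 higher, median −0.08, and −0.06 with both extra-transcript libraries left out). Each set came from another day of control than the day tested, so set and test shared no libraries.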

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

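Of the tests given here, only the splits of the samples and the quantile normalization of the day 4 muscle list were written before the results were seen, and the other tests were chosen only after the result was seen.

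The effect of 5 µM changed between days for 751 genes from day 1 to day 2, 4079 from day 1 to day 4 and 3074 from day 2 to day 4, and the effect of 2 µM changed for 221 from day 1 to day 4. Between days 1 and 4 the 5 µM effect moved by −0.57 for Myod1, 1.44 for Myf5, −0.94 for Mef2c, 0.74 for Tmem8c, −1.13 for Gm7325, 1.17 for Acta1 and 1.16 for Ckm. Stress genes moved by 1.60 for Mt1, 2.31 for Mt2, 0.85 for Hmox1, 2.14 for Nqo1, 2.63 for Ddit3, 1.27 for Fbxo32 and 0.61 for Hspa5. Cdkn1a moved by −0.41, Mki67 by −3.24 and Col1a1 by −3.95.

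The samples of each comparison can be split into groups of 3 in 10 ways, too few for a share under 0.05, and the true split gave the most called genes each time, 1 of 10. For differentiation the true counts were 6226, 6713 and 7736, with at most 0, 0 and 2 for any other split. For 5 µM they were 1774, 3063 and 7228 against 12, 0 and 2, and for 2 µM 258, 66 and 1145 against 2, 0 and 1. Between doses they were 717, 1653 and 6163 against 83, 0 and 1. For the changes of effect between days, 10, 13 and 8 of 100 relabellings at 5 µM and 6 of 100 at 2 µM gave as many genes as the true labels. Every one of these kept the groups of 1 day whole, so chance is not excluded by this count and the count follows the structure of the samples. The highest count from a relabelling that kept no day whole was 0, 1, 0 and 6. Splits and relabellings that mix the true groups put any true difference into the spread, so their low counts are no measure of chance.

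The adipose transcripts of replicate 1 at 2 µM on day 1 came with Y-linked genes at a median of 9.53 CPM, while the highest Y-linked value in the other libraries was 0.379 CPM. A response of the treated cells would be shared by replicates, and the median log2 difference of 16 adipocyte markers from control was 3.98 in replicate 1 and 0.00 in replicates 2 and 3. RNA from adipocytes of a male mouse in that library is therefore the likely source, as a hypothesis from marker lists written before the test. Leptin (Lep) stood at 0 CPM there, and the blood cell genes Ptprc, Cd74 and Igkc at 0.0808, 0 and 0 CPM. Whether the adipocytes came from tissue or from culture was not tested. The most abundant genes were Fabp4 at 2530 CPM and Hp at 2070 CPM.

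In replicate 3 at 5 µM on day 1, 21 of 30 lung, neuroendocrine and blood genes reached 5 CPM while staying below 1 CPM elsewhere, 11 of 15, 7 of 10 and 3 of 5 by list. Of the 30, 6 were also above 1 CPM in other libraries (Foxj1, Chil1, Syp, Scg5, Uchl1 and Hba-a1). An induction by Cr(VI) is argued against by the other replicates, whose median log2 difference was 0.00 against 4.03 in replicate 3. RNA from lung tissue with neuroendocrine cells could be the source, as a hypothesis, with Sftpc at 199 CPM and Lyz2 at 184 CPM. No Y-linked reads were seen there.

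The low muscle genes at 5 µM on day 4 could come from scaling, from delay or from a separate change of state. Quantile normalization left the adult sarcomere median at −1.85 against −1.89. The median log2 change over all genes was already −0.01, so this normalization had little to move. The fall was thus not a shift of all genes in these values, but relative values cannot show a change in RNA per cell. Of all 7228 genes called, 918 (12.7%) lay 2-fold or more outside the levels of all 4 control days, 318 above and 600 below. This argues against delay as the whole cause of the changes over all genes. It does not bear on the muscle genes, since the 918 included all 30 G2/M genes and 0 of 32 adult sarcomere genes. Of 105 muscle genes that fell, 3 lay 2-fold or more below every control day. Among the 43 of them whose lowest control day was at 5 CPM or more the share was 6.98% (3 of 43, interval 1.46 to 19.1% by the Clopper-Pearson method). Delay and a lasting block can both leave muscle genes within the levels of the control days, so this share cannot tell them apart. The rule for reading this share was changed to its interval after the share was seen, and the rule written earlier would have argued against delay.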

How the results depend on the processing

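All settings here were planned before the data were examined, except leaving out both libraries with foreign transcripts, among the tests chosen only after the result was seen.

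Of the counts of genes under other settings, 843 stayed within 1.5-fold, 25 were larger and 74 smaller. Of the named gene results, 26058 kept their call, 111 gained one, 1324 lost one and 2 reversed. Of the list results, 7420 kept their call, 86 gained one, 240 lost one and 6 reversed. The 5 µM counts on days 2 and 4 and the differentiation counts never moved more than 1.5-fold. At 2 µM on day 2 the 66 genes became 129 with a pseudocount of 4, 38 with no filter, 181 with DESeq2, 324 with only the groups of the comparison and 125 with both libraries left out. Leaving out single libraries gave 25, 24 and 30 without a control and 31, 23 and 19 without a treated replicate. The smaller sample is the construction cause there. Both libraries with foreign transcripts lie outside this comparison, so the 125 came through the spread shared by the fit. Elsewhere the cause was not tested.

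On day 1 at 2 µM the 258 genes became 460 with DESeq2, 115 with both libraries left out, 87 without treated replicate 1, 464 without treated replicate 2, and 138, 161 and 135 without each control. With only the groups of the comparison limma gave 0, with 1289 at unadjusted p below 0.05 and DESeq2 was run on all 30 libraries only, with 460. That setting also gave 855 for 5 µM on day 1, 24 for 5 against 2 µM on day 1, 445 for 2 µM on day 4 and 64 for the change of the 2 µM effect from day 1 to day 4. That last count was 400 with DESeq2, 141 without treated replicate 1 of either day and 328 without treated day 1 replicate 2. For 5 against 2 µM on day 1 both libraries left out gave 405.

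Some lists and genes turned. The matrix list at 2 µM on day 1 went from 0.00 to −0.14 without replicate 1 and with both libraries left out. For 5 against 2 µM on day 1 the G1/S median went from 0.03 to −0.25 with both left out and −0.20 without 5 µM replicate 3, and was 0.20 without 5 µM replicate 2. The adipocyte median went from −0.95 to 0.26 with both left out and 0.25 without 2 µM replicate 1, and was −1.55 without replicate 2. Mt2 went from −0.37 to 0.61 and 0.52 in those settings, and to −0.87 without 2 µM replicate 3.

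Replicate numbers did not pair libraries, with mean same-number correlations of −0.10 to 0.07, and a replicate block gave 1772 genes for 5 µM on day 1 and 251 for 2 µM.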

Other observations

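The comparison with the nearest control day was among the tests chosen only after the result was seen. Some genes at 5 µM on day 4 lay outside every level that control cells passed through in 4 days. Against the nearest control day Clec3b was higher by a log2 of 3.73, Mmp3 by 3.64, Smtnl1 by 3.55, Cxcl13 by 2.86, Tppp3 by 2.67, Mgst1 by 2.56, Gstm1 by 2.53 and Osgin1 by 2.50. All 30 G2/M genes lay 2-fold or more below every control day, as did 12 of 28 G1/S, 15 of 32 matrix and 10 of 31 DNA repair genes. Only 4 of 28 NRF2 targets lay above every control day.

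The rise of NRF2 targets at 5 µM thus ran against a normal loss. Nqo1 stood at 54.7 ± 5.31 CPM on day 4 at 5 µM, against 151 ± 10.9 CPM in undifferentiated controls and 6.35 ± 2.36 CPM in day 4 controls (SD, n = 3). Myf5 at 94.1 ± 6.31 CPM exceeded its day 0 level of 54.5 ± 6.90 CPM, while Pax7 fell by 1.40 at 5 µM on day 4. Both inhibitors Cdkn1a and Cdkn1c fell at 5 µM on day 4 (by 0.72 and 3.91), and division genes fell too. The fall of Cdkn1a was less than 2-fold from 2900 ± 311 CPM, which left it above its day 1 control level of 685 ± 42.1 CPM.

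Some genes fell early and others rose late. At 5 µM on day 2 Asns fell by 2.45, Phgdh by 2.39 and Mthfd2 by 2.49, while Ddit3 did not pass. On day 4 Ddit3 rose by 2.85 and Atf3 by 2.98, and Hspa5 fell by 0.58.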
